A study of Mus musculus with 2 samples.

How the data were processed

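Sap130 occupancy was measured by ChIP-seq in embryonic mouse heart, with 1 library from a Sap130 antibody and 1 input library, both labelled as wild-type B6. Per the labels' protocols, chromatin was precipitated with a rabbit antibody and a commercial kit for transcription factors, and libraries were made with a commercial DNA library kit for Illumina sequencing. The age labels differ, E13.5 for the ChIP library and E13.6 for the input. The submitters' processing notes name Bowtie 1.1.2, a short-read aligner, MACS2 2.1.0.20140616, a peak caller that tests ChIP reads against an input background, and the builds GRCm38 and mm10, which hold the same chromosome sequences. Parameters, thresholds, duplicate handling, region filters and how the gene columns were made are not given in the sources used here. These choices could change the number and width of peaks, and regions of high artefactual signal may or may not have been removed.

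The authors deposited 1 peak table for the 2 libraries. It gives, per the file headers, a row number, chromosome, start, end, a strand entry that is + throughout, and a gene annotation. Unnamed columns hold a transcript accession with its strand, span, coding span and exons. The table used here has no summit, pileup, fold enrichment, p-value or q-value, and no read counts, so the depth of the libraries is unknown and no precision per peak could be given. Peaks were not called per replicate, since there was 1 ChIP library. Transcript starts count from 0: with 1 added, 45.9% of 11692 matched accessions started at the gene start of the 1-based reference table, whose gene spans cover all transcripts of a gene. They are printed with 1 added. Peak positions are printed as deposited. Whether they count from 0 or 1 is not stated, so they are uncertain by 1 bp.

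Peaks were linked to genes through the accession in the table, matched without version to a RefSeq gene table of assembly GRCm38.p6 on the same chromosome. Of 15171 peaks with a gene named, 14986 matched by accession, 135 by symbol and 25 by synonym, and 25 did not match. Every named peak's midpoint lay within 10 kb of the start of its transcript. A promoter peak is a peak whose midpoint lies within 1 kb of the start site of the transcript named for it. The background for gene lists was the 20953 protein-coding genes with a curated RefSeq transcript on the autosomes and the X chromosome. The table used here holds 0 peaks on chromosome Y and 0 on unplaced contigs, and the mitochondrial peaks were left out of gene comparisons. The gene table gives no strand, so for genes that the peak table does not name it is unknown which end is the start.

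The following were fixed before the data were examined: 26 gene lists, the promoter window, Fisher's exact test per list with Benjamini-Hochberg adjustment at 0.05, and the rule for named genes. The rule names the 20 genes with the strongest promoter peaks, the 4 strongest members and up to 3 members without a promoter peak in each list, 11 genes chosen for the complex, the heart and its defects, and the 5 widest and 5 strongest distal peaks. Some genes that the rule names are not reported here. Strength was to be fold enrichment. As the table gives none, the authors' order was used in its place, and the order's criterion is not stated. Of the listed genes, 1 (Pkd1l1) was not found in the background. The planned comparison of fold enrichment between promoter and distal peaks, the CpG content of promoters, the motif counts at summits, the share of genome sequence in promoters, and alternatives on q, fold or CpG content need values or sequence not used here and were not run. Midpoints stood in for summits.

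The following 2 comparisons were added after the data were seen. The position of each list in the authors' order was set against 10000 random lists of genes with a promoter peak. The share of peaks near gene ends was set against 1000 circular shifts of the peaks along each chromosome, up to the end of its last annotated gene. The list test was tested on simulated data with the real genes in 200 simulations. Each gene was drawn independently, and genes of the lists with a planted effect were left out of the other lists. With a planted odds ratio of 4 it called the 45 cardiac transcription factors in 95% of simulations and the 79 splicing factors in 99.5%. With a planted odds ratio of 0.25 it called the 40 neuronal genes in 89.5% and the 39 Hox genes in 89%. Lists without a planted effect were called in 0.886% of tests. Linked calls of neighbouring or related genes were not simulated, so this share need not hold in the real data. Alternatives were windows of 500 bp and 3 kb, any base of the peak in place of its midpoint, autosomes only, gene names at any distance, merged peaks, the first part of the order, wide peaks, either gene end and a background without chemosensory receptor and keratin genes. Calculations used Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.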

Results

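Sap130 occupancy was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the heart of wild-type (B6) mouse embryos. Sap130 is a subunit of the Sin3 histone deacetylase complex, which removes acetyl groups from histone tails. The study holds 2 libraries, 1 immunoprecipitated with a Sap130 antibody at embryonic day E13.5 and 1 input library of unenriched chromatin, whose age label reads E13.6. The question the design states is which genomic targets Sap130 occupies in the embryonic heart. With 1 library of each kind there are no replicates, so every interval and test given here describes this peak list and not the spread between hearts. The authors' table gives 16697 peaks by position, called on 1 ChIP library against 1 input, and names a transcript within 10 kb for 15171 of them. Positions are the authors' own. The columns used here hold no read depth, peak height, fold enrichment or p-value per peak, so the depth of each library is unknown. Intervals are 95% exact Clopper-Pearson intervals and cover counting error only.

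Sap130 peaks lay mostly at gene starts. The midpoint of 12760 of the 16697 peaks, 76.4% (95% interval 75.8 to 77.1), lay within 1 kb of the transcription start site of the transcript named for it. Of these promoter peaks, 73.7% contained the start site itself, and 78.3% had their midpoint downstream of it, in the first exon for 37.5% and in an intron or later exon for 40.5%. The median named peak was centred 205 bp downstream of its start site, with quartiles at 18.8 and 442 bp. Another 6.9% of peaks were centred in introns 1 to 10 kb downstream of the start site, 4.55% lay 1 to 10 kb upstream, and 1.49% lay in coding exons. Peaks with no start site named within 10 kb numbered 1526. Of these, 910 lay inside a protein-coding gene, 185 inside another annotated gene, 425 between genes and 6 on mitochondrial DNA. Chance placement was assessed by shifting all nuclear peaks along their chromosomes 1000 times, a comparison chosen after the data were seen. Of the nuclear peaks, 67.1% had their midpoint within 1 kb of either end of a protein-coding gene, against a mean of 3.05% and a highest value of 4.12% among the shifted sets, a 22.0-fold difference. Either end was used there because the gene table gives no strand, and the fold depends on the window, as given in the closing section.

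Peaks were between 207 and 6332 bp wide, with a median of 682 bp and quartiles of 382 and 1087 bp. Promoter peaks had a median width of 785 bp and the other peaks one of 384 bp. The widest peak, 6332 bp, spanned the promoter of Gata6, a cardiac and endodermal zinc finger transcription factor (mm10, chromosome 18, 11050134 to 11056466). The next widest, of 5429 bp, was centred in an intron of Smad6, an inhibitor of BMP signalling (chromosome 9, 64016693 to 64022122). Its centre lay 2652 bp downstream of the start site, which the peak contains. Then came a peak of 5062 bp centred in an exon of the non-coding RNA gene Malat1 (chromosome 19, 5797772 to 5802834). Its centre lay 2368 bp downstream of the start site, which this peak also contains. The fourth, of 4837 bp, lay at the promoter of Brd2, a reader of acetylated histones (chromosome 17, 34116985 to 34121822). The fifth, of 4730 bp, lay at the promoter of Zc3h4 (chromosome 7, 16399228 to 16403958).

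The table is not sorted by chromosome, and the criterion of its order is not given in the sources used here. The order carried information on the peaks. Across peaks, which are not independent replicates, position in the order and width were inversely related, with a Spearman rho of -0.76. Among the first 1000 peaks the median width was 1192 bp and 96.4% were promoter peaks. Among the last 697 peaks the median width was 251 bp and 45.2% were promoter peaks, while the share with no start site named within 10 kb was 1.7% in the first 1000 and 19.2% in the last 697. Positions are therefore given below as a rank within this list, counted from 1 at its top, with no unit of binding attached.

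**Figure D1:**
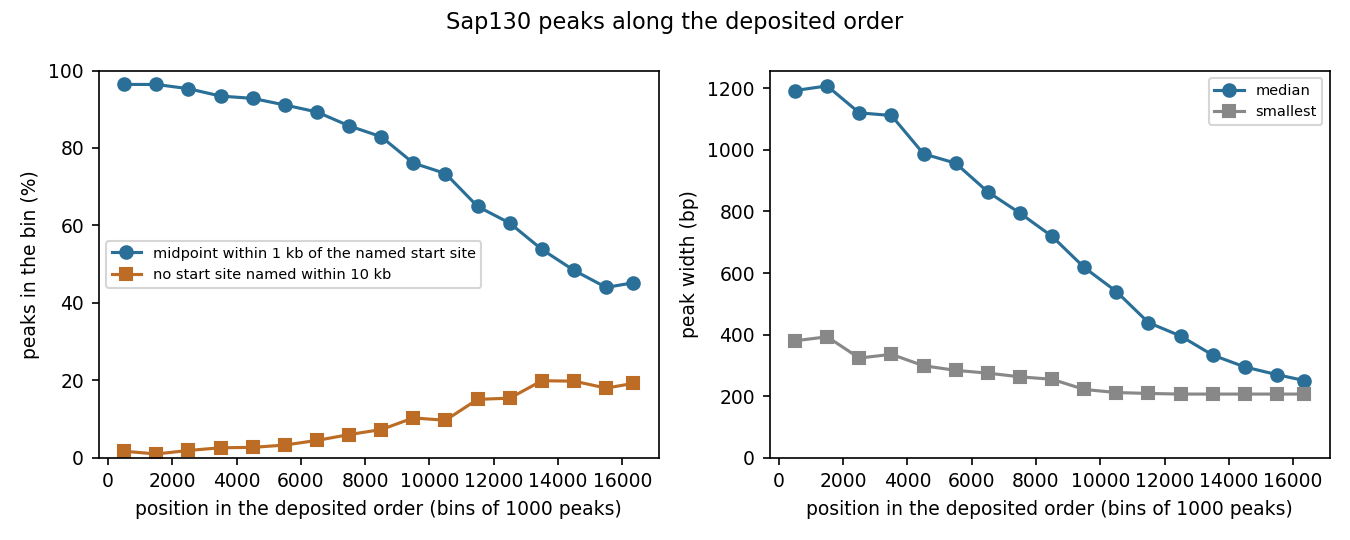
The left plot gives, for bins of 1000 peaks along the deposited order (x axis, position), the percentage of peaks centred within 1 kb of the named start site and the percentage with no start site named within 10 kb; the right plot gives the median and the smallest peak width in bp. The promoter percentage goes from 96.4% in the first bin to 45.2% in the last, and the median width from 1192 to 251 bp.

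The 20 protein-coding genes whose promoter peaks came first were Trmt61a (position 1), Ddx21 (2), Ncl (3), Nol9 (4), Gar1 (7), Rrp12 (9), Crebrf (10), Ccne2 (11), Utp20 (12), Vars (13), C1qbp (14), Bub1 (15), Hsf1 (16), Wee1 (18), Mettl1 (19), Pprc1 (20), Trmt2a (21), Dyrk1b (22), Scfd2 (23) and Nop2 (24). Ncl encodes nucleolin, the main RNA-binding protein of the nucleolus, Ddx21 an RNA helicase of ribosomal RNA synthesis, and Gar1 a core protein of box H/ACA ribonucleoproteins. Nol9, Rrp12, Utp20 and Nop2 encode processing factors of ribosomal RNA. Trmt61a, Trmt2a and Mettl1 encode tRNA methyltransferases and Vars a tRNA synthetase. Ccne2 encodes cyclin E2, Bub1 a kinase of the spindle checkpoint and Wee1 the kinase that restrains entry into mitosis. The first peak, at Trmt61a, was 1181 bp wide (chromosome 12, 111677738 to 111678919) and centred 224 bp downstream of the start site. The peak at Ncl (chromosome 1, 86358133 to 86359403) was centred 687 bp downstream and did not reach the start site at 86359455. A separate peak just upstream of that site, at 86359504 to 86360376 (position 1969), was named for the non-coding gene C130036L24Rik.

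Of the first 1000 peaks, 96.4% were promoter peaks, and the first 5 of the others stood at positions 5, 6, 8, 17 and 33. Position 5 lay between genes, 33893 bp from the nearest protein-coding gene Foxk1 (chromosome 5, 142367115 to 142368093). Position 6 was centred upstream of Gm16532, at -4918 bp from the start site (chromosome 7, 6410004 to 6410509), and position 8 lay in the 3′ UTR of the taste receptor gene Tas1r3 (chromosome 4, 155859145 to 155859749). Positions 17 and 33 lay inside Phf21b (chromosome 15, 84829338 to 84829854) and Erich1 (chromosome 8, 14072532 to 14072946), with no start site named within 10 kb.

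Of 20953 protein-coding genes on the autosomes and the X chromosome, 10601 had a promoter peak, 50.6% (49.9 to 51.3). Each peak names a single gene, so a gene that shares its start region with a neighbour can go unnamed. Of the 10352 genes without a promoter peak, 1316 had a peak centred within 1 kb of either end. The 26 gene lists fixed before the data were examined were each compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted over the 26 lists by the Benjamini-Hochberg method. The share of members with a promoter peak was higher than in other genes in 17 lists, lower in 6 and not distinguishable in 3. Genes are not replicates, and the test says nothing on other hearts. The background holds genes whether or not they are expressed in heart, and no expression data or sequence were used. Whether a higher share reflects active or CpG-rich promoters in general was therefore not tested for any list. The only control was input chromatin, so the specificity of the antibody was not tested. Some genes belong to several lists, so the calls are not independent.

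**Figure D2:**
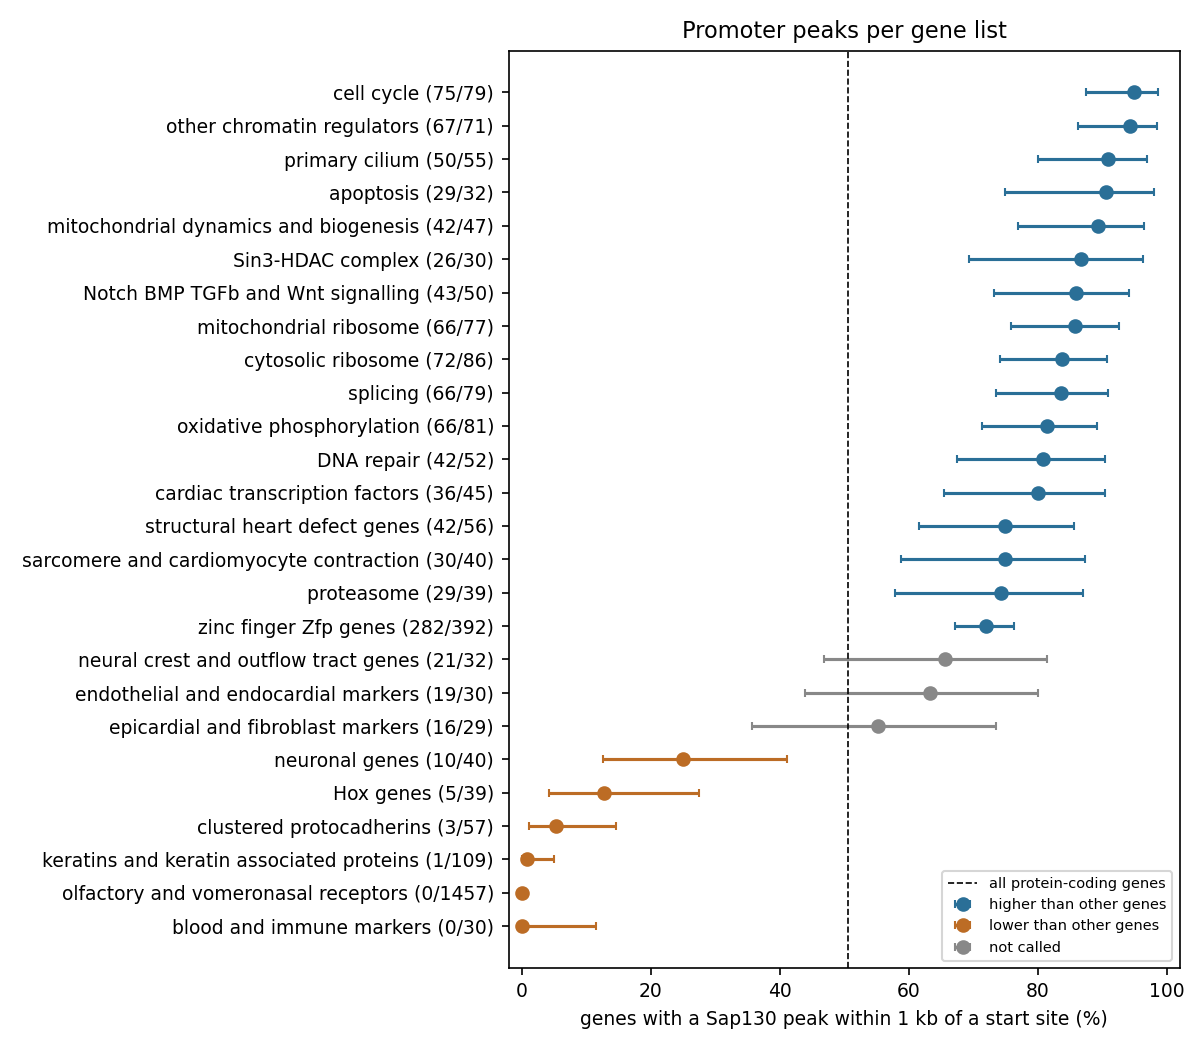
Each point is the percentage of a list's genes with a Sap130 peak centred within 1 kb of a start site (x axis), with its 95% exact interval; counts stand in brackets and the dashed line marks all protein-coding genes at 50.6%. Cell cycle genes stand at 94.9%, and olfactory and vomeronasal receptors and blood and immune markers stand at 0.

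Genes of the Sin3 complex and its partners mostly carried promoter peaks. Of 30 genes of the complex and its partners, 26 had a peak, 86.7% (69.3 to 96.2) against 50.5% of other genes (Fisher's exact test, adjusted p = 8.78e-05). Sap130 itself had 2 peaks at its promoter, the earlier at position 5952 (chromosome 18, 31633719 to 31634894), which spans the start site at 31634383. Sin3a, the scaffold of the complex, had 4 named peaks within 10 kb of its annotated start sites, the earliest at position 1649 (chromosome 9, 57076358 to 57077499). The deacetylase genes Hdac1 and Hdac2 had promoter peaks at positions 7720 and 6480. The earliest members were Suds3 (position 293), Arid4a (861), Ing1 (943) and Sap30 (1070). Sap18, Kdm5a and Tet1 had no promoter peak, although each had a peak within 1 kb of an end of the gene. With a window of 500 bp in place of 1 kb, 16 of 30 genes were counted and the list was no longer called (odds ratio 1.37 in place of 6.36).

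Other chromatin regulators had promoter peaks in 67 of 71 cases, 94.4% (86.2 to 98.4, adjusted exact p = 5.34e-15). Prmt1, an arginine methyltransferase, stood at position 86, the chromatin remodelling subunits Pbrm1 and Ino80 at 107 and 115, and Wdr5, a core subunit of histone H3 methyltransferases, at 109. Kdm6b, Chd8 and Gatad2b had no promoter peak but had a peak within 1 kb of an end of the gene, and for Kdm6b the nearest named peak was centred upstream, at -1954 bp from the start site.

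Cell cycle genes had a promoter peak in 75 of 79 cases, 94.9% (87.5 to 98.6, adjusted exact p = 4.16e-17), led by Ccne2, Bub1, Wee1 and the mitotic cyclin gene Ccnb2 (position 43). The 4 without one included Ccnd2 and Cdkn1c, whose nearest named peaks were centred at -1038 and 1022 bp from the start site, and Foxm1, which had a peak within 1 kb of an end of the gene. DNA repair genes had a peak in 42 of 52 cases, 80.8% (67.5 to 90.4, adjusted exact p = 1.45e-05), with Ung (151), Ddb1 (603) and H2ax (915) first. Atm, Atr and Brca1 were among the 10 without a promoter peak, of which 8 had a peak at an end of the gene. Apoptosis genes had a peak in 29 of 32 cases, 90.6% (74.98 to 98.0, adjusted exact p = 4.28e-06), with Diablo (55), Bax (279), Bmf (1199) and Bad (1332) first. Bcl2l11, Pmaip1 and Birc2 had none, and the nearest named peaks of Bcl2l11 and Birc2 were centred at 1037 and -1902 bp from the start site.

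Genes of mitochondria and of protein synthesis and turnover were also bound more often than other genes. Genes of mitochondrial dynamics and biogenesis had promoter peaks in 42 of 47 cases, 89.4% (76.9 to 96.5, adjusted exact p = 5.22e-08). The earliest were Pprc1 (20), a coactivator related to PGC-1, the chaperone genes Hspd1 (114) and Hspa9 (119), and Immt (168), while Mief2, Fundc1 and Tfb2m had none. Nuclear genes of oxidative phosphorylation had peaks in 66 of 81 cases, 81.5% (71.3 to 89.2, adjusted exact p = 2.09e-08), led by Ndufv1 (198), Cox4i1 (1239), Uqcrq (1391) and Ndufb5 (1496). Atp5h, Atp5j and Atp5pb had no promoter peak, and 12 of the 15 such genes had a peak at an end of the gene. Mitochondrial ribosomal proteins had peaks in 66 of 77 cases, 85.7% (75.9 to 92.6, adjusted exact p = 4.44e-10), led by Mrps6 (308), Mrpl2 (316), Mrpl12 (455) and Mrpl43 (464), with none named for Mrpl13, Mrpl18 and Mrpl21. Cytosolic ribosomal proteins had peaks in 72 of 86 cases, 83.7% (74.2 to 90.8, adjusted exact p = 5.40e-10), led by Rpsa (66), Rps19 (68), Rplp0 (237) and Rplp1 (303). Rpl10l, Rpl13 and Rpl15 had none named within 1 kb. Counts of ribosomal protein genes can be affected by reads shared with their many pseudogenes. Splicing factors had peaks in 66 of 79 cases, 83.5% (73.5 to 90.9, adjusted exact p = 2.87e-09), with Lsm2 (81), Srsf7 (140), Srsf2 (167) and Srsf10 (228) first. Hnrnpa1, Hnrnpk and Hnrnpu were without one, and Hnrnpu had a peak at position 230 centred 1372 bp downstream of its start site. Proteasome subunits had peaks in 29 of 39 cases, 74.4% (57.9 to 87.0, adjusted exact p = 0.00388), led by Psmd4 (494), Psmd3 (846), Psma3 (1473) and Psmb1 (1640), with none named for Psma4, Psma7 and Psma8. Genes without a promoter peak also often had a peak at an end of the gene in the other lists of this paragraph: 4 of 5 for mitochondrial dynamics, 10 of 11 for mitochondrial and 11 of 14 for cytosolic ribosomal proteins, 11 of 13 for splicing and 7 of 10 for the proteasome.

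Cardiac transcription factors had promoter peaks in 36 of 45 cases, 80% (65.4 to 90.4, adjusted exact p = 9.30e-05). The earliest were the MADS-box factors Mef2d (969), Srf (1507) and Mef2a (2106) and the retinoic acid receptor Rara (1929). Of these, Rara had 7 named peaks within 10 kb, Mef2d 5, Srf 4 and Mef2a 1. The core cardiac regulators stood later, also with several peaks each. Gata4 had 8 named peaks within 10 kb of its start site, the promoter peak being 1975 bp wide at position 6705 (chromosome 14, 63244038 to 63246013). Nkx2-5 had 7, the earliest at position 8663 (chromosome 17, 26840935 to 26841565). Tbx5, Tbx18 and Tbx20 had no promoter peak. Tbx5 had 5 named peaks within 10 kb, the nearest centred 1045 bp downstream, and Tbx20 had 6, among them a peak of 4624 bp that contains the start site and is centred 1847 bp downstream. The list was not called with a 500 bp window, which counted 27 of 45 genes (odds ratio 1.80 in place of 3.92), or among the first 8348 positions, which counted 22 (1.83).

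Genes of the contractile apparatus and calcium handling had promoter peaks in 30 of 40 cases, 75% (58.8 to 87.3, adjusted exact p = 0.00267), most of them late in the list. The earliest were Nppb (118), the gene of the natriuretic peptide BNP, Atp2a2 (1771), the calcium pump of the sarcoplasmic reticulum, Tpm1 (5770) and Cacna1c (5915). The myosin heavy chain genes Myh6 and Myh7 had promoter peaks at positions 14438 and 16575, of 226 and 378 bp. These were centred 226 and 972 bp downstream of the start site, and neither contained it. No peak was named for Myl4, Acta1 and Myom2. The direction turned with the peaks used, from an odds ratio of 2.94 to 0.272 among the first 8348 positions, where 5 of 40 genes had a promoter peak, and to 0.418 among peaks at least as wide as the median. In both cases the list was called lower than other genes. The list was also not called with a 500 bp window (1.62) or with a peak at either end of the gene (1.04).

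**Figure D3:**
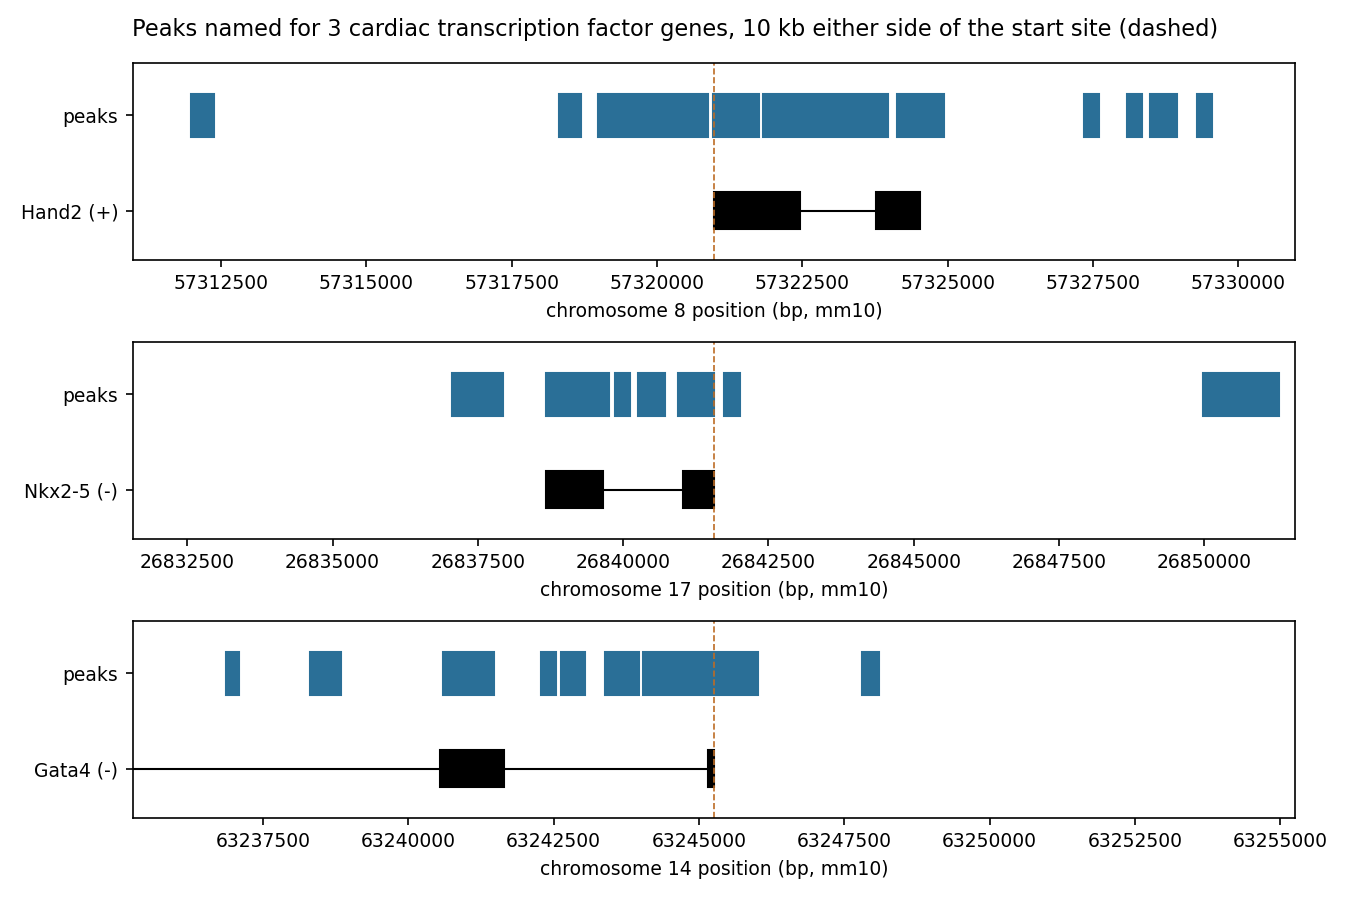
Each plot spans 10 kb either side of the start site (dashed line) of Hand2, Nkx2-5 or Gata4 on the mm10 chromosome named on the x axis in bp; blue boxes are the peaks named for the gene, black boxes its exons and the line its introns. Hand2 has 10 peaks, Nkx2-5 has 7 and Gata4 has 8.

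Genes of the Notch, BMP, TGF-beta and Wnt pathways had promoter peaks in 43 of 50 cases, 86% (73.3 to 94.2, adjusted exact p = 4.13e-07). Axin1 (779), Tgfbr1 (1218), Smad2 (1388) and Ctnnb1 (1543) came first, and Notch1 had a peak of 2518 bp at position 5527 (chromosome 2, 26501650 to 26504168). No peak was named for Notch4, and the named peaks nearest to Dll4 and Hes1 were centred at -3112 and 1003 bp from the start site. Genes known from structural heart defects had promoter peaks in 42 of 56 cases, 75% (61.6 to 85.6, adjusted exact p = 0.000316), with Mks1 (362), Fbn2 (1118), Smarca4 (1138) and Kmt2d (1142) first. The heart defect list shares members with other lists, among them Mks1 with the cilium list and Smarca4 and Kmt2d with the chromatin regulators. Pcdha9, a protocadherin gene linked together with Sap130 to left heart hypoplasia in mice, had no peak named for it, nor had Robo4. With a 500 bp window the pathway list (odds ratio 1.30 in place of 6.02) and the heart defect list (1.29 in place of 2.94) were not called, and the latter was also not called among the first 8348 positions (1.65) or with a peak at either end of the gene (1.57). Genes of the primary cilium had promoter peaks in 50 of 55 cases, 90.9% (80.0 to 96.98, adjusted exact p = 6.73e-10), led by Ift52 (270), Kif3b (297), Ift57 (332) and Mks1. Ift20, Ift140 and Cep290 were among the 5 without a promoter peak, of which 4 had a peak at an end of the gene. Zinc finger genes named Zfp had promoter peaks in 282 of 392 cases, 71.9% (67.2 to 76.3, adjusted exact p = 4.16e-17), led by Zfp869 (243), Zfp316 (524), Zfp568 (525) and Zfp202 (610), with no peak named for Zfp108, Zfp114 and Zfp119a. Among peaks at least as wide as the median neither the cilium list (odds ratio 1.22 in place of 9.81) nor the Zfp list (1.06 in place of 2.54) was called, and the Zfp list was not called among the first 8348 positions (1.06).

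Markers of endothelial, epicardial and neural crest cells were not distinguishable from other genes at this setting, and blood and immune markers stood below them. Endothelial and endocardial markers had promoter peaks in 19 of 30 cases, 63.3% (43.9 to 80.1, adjusted exact p = 0.209), with Nfatc1 (4787), Ramp2 (5073), Kdr (6106) and Egfl7 (7252) first, no peak named for Tie1 and Emcn, and 1 peak centred 1963 bp downstream of the Cdh5 start site. Epicardial and fibroblast markers had them in 16 of 29 cases, 55.2% (35.7 to 73.6, adjusted exact p = 0.711), with Fn1 (6512), Vim (6548), Twist1 (9156) and Wt1 (9483) first and none at Tcf21, Tbx18 and Upk3b. Neural crest and outflow tract genes had them in 21 of 32 cases, 65.6% (46.8 to 81.4, adjusted exact p = 0.120), with Dvl1 (681), Dvl2 (1654), Crkl (3949) and Plxnd1 (4954) first. Tfap2b and Sox10 had no named peak, and Tfap2a had 1, centred 7126 bp downstream. None of 30 blood and immune markers had a promoter peak (upper bound of the interval 11.6%), against 50.7% of other genes (adjusted exact p = 1.66e-09), while 2 of the 30 were named by a peak within 10 kb. Neural crest genes were called higher with a 3 kb window (odds ratio 2.39 in place of 1.87), and among the first 8348 positions the odds ratios of the endothelial, epicardial and neural crest lists were 0.693, 0.141 and 0.745. The epicardial list, with 2 of 29 genes, was called lower there. The globin genes Hba-a1, Hba-a2 and Hbb-bt had no named peak.

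Neuronal, Hox, clustered protocadherin, keratin and chemosensory receptor genes had promoter peaks less often than other genes. Neuronal genes had promoter peaks in 10 of 40 cases, 25% (12.7 to 41.2, adjusted exact p = 0.00160), with Grin1 (3480), Snap25 (4572), Stx1a (6877) and Elavl4 (7097) first and none at Syp, Syt1 and Syn1. Hox genes had them in 5 of 39 cases, 12.8% (4.3 to 27.4, adjusted exact p = 1.86e-06), among them Hoxd1 (14951), Hoxd8 (15652) and Hoxa5 (16424), and none at Hoxa10, Hoxa11 and Hoxa13. Clustered protocadherin genes had them in 3 of 57 cases, 5.26% (1.1 to 14.6, adjusted exact p = 5.61e-13), namely Pcdhgc3 (8598), Pcdhgc4 (11420) and Pcdhga10 (15641). No alpha cluster gene was among them, and Pcdha1, Pcdha10 and Pcdha11 had no peak named for them. Of the 54 without a promoter peak, 18 had a peak at an end of the gene, and with either end counted the list held 21 of 57 (odds ratio 0.549 in place of 0.0540) and was still called lower. Genes of a cluster can share their far end: Pcdhgc3 and Pcdhgc4 both end at 37841873 and Pcdhga10 at 37841870. A single peak there can count for many genes, so the either-end count does not bear on their start sites. Of 109 keratin and keratin-associated genes, only Krt19 (15302) had a promoter peak (adjusted exact p = 5.19e-31). Krt1 and Krt12 had no named peak and Krt10 had 1, centred 3108 bp downstream. None of 1457 olfactory and vomeronasal receptor genes had a promoter peak (upper bound of the interval 0.253%), against 54.4% of other genes. The two-sided exact p was too small to compute. The log10 of the unadjusted one-sided hypergeometric p was -470. Olfr1, Olfr10 and Olfr100 had no named peak.

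Among genes with a promoter peak, the lists also stood at different positions. This comparison was chosen after the data were seen, in place of a planned comparison of fold enrichment. The median position of the first promoter peak was 5882 over all 10601 genes. For each list with at least 3 such genes, the median was set against 10000 random lists of the same size drawn from those genes. Of 23 lists, 6 stood earlier than the central 95% of the random lists, 6 later and 11 within it. Genes of the Sin3 complex and its partners (median position 2030), cell cycle genes (2729), cytosolic ribosomal proteins (2864) and other chromatin regulators (2942) stood earlier than every random list. Splicing factors (3316) and genes of mitochondrial dynamics (3336) stood earlier than all but 0.02% and 0.18% of the random lists. Within the Sin3 list, Suds3 (293) and Sin3a (1649) stood ahead of the median of all such genes. Sap130 (5952), Hdac2 (6480) and Hdac1 (7720) stood behind it. Sarcomere genes (12371), epicardial and fibroblast markers (12038) and Zfp genes (8418) stood later than every random list. Hox genes (15652), endothelial markers (9866) and neural crest genes (9379) also stood late, at percentiles 99.99, 99.67 and 99.36, the Hox median resting on 5 genes. Cardiac transcription factors (7638) stood at the 95.01th percentile, within the random range, while their first promoter peaks were wide, with a median of 1348 bp against 857 bp over all genes. The first promoter peaks of every early list except mitochondrial dynamics were wider than the random range, and those of the sarcomere, epicardial, Hox and Zfp lists were narrower. The calls of early and late in this paragraph were not matched on width or on the number of peaks per gene. A gene with several promoter peaks was placed by its earliest, which favours an early position.

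**Figure D4:**
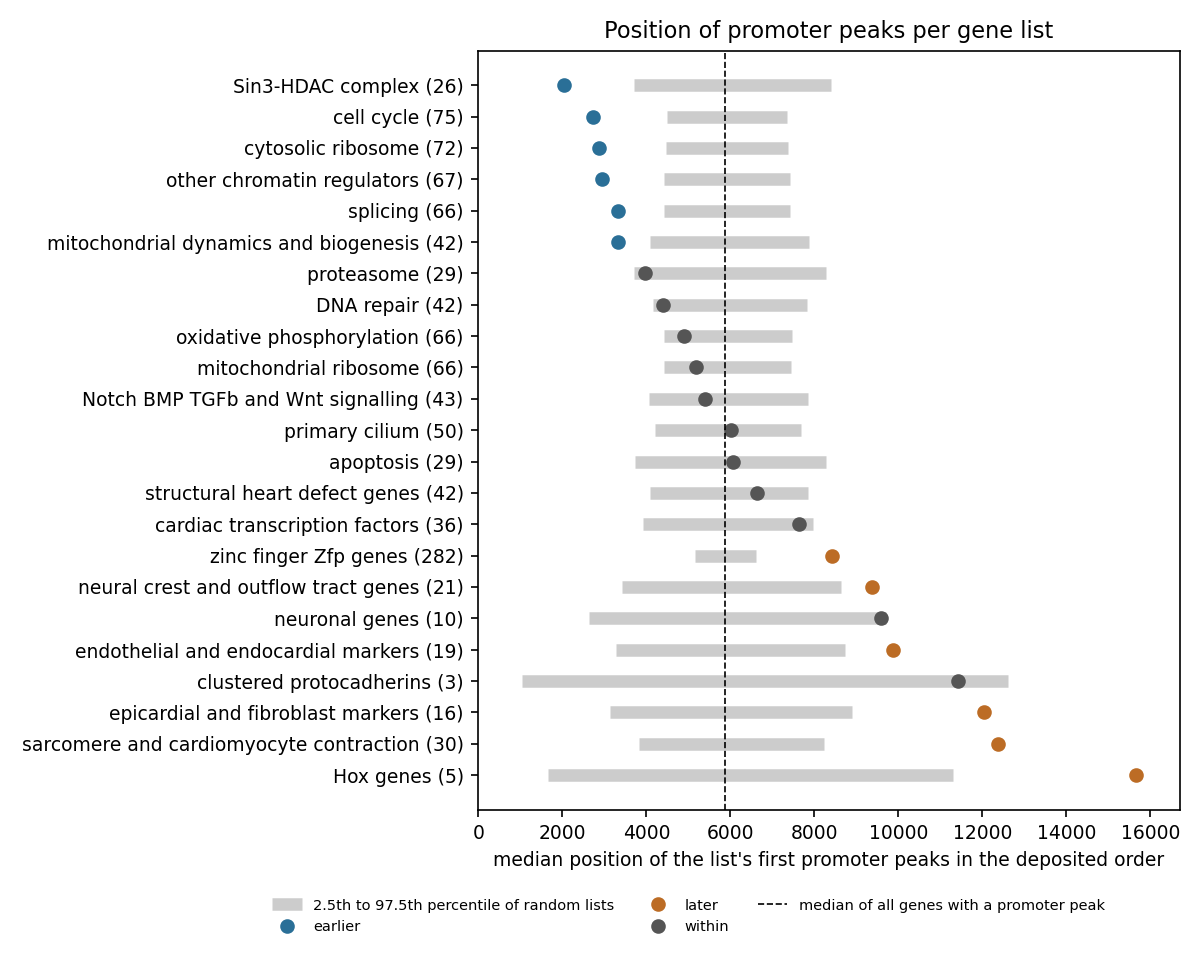
Each point is the median position of a list's first promoter peaks in the deposited order (x axis), with the number of genes in brackets; grey bars span the central 95% of 10000 random lists of the same size and the dashed line is the median of all genes with a promoter peak, 5882. The list of the Sin3 complex and its partners stands first at 2030 and Hox genes last at 15652.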

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

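The test here was chosen after the peaks were seen. Outside the nuclear chromosomes that the comparisons use, the table holds 6 peaks on mitochondrial DNA, at positions 12343 to 13305 of the authors' order. They overlap both ribosomal RNA genes and ND1, ND2, ND4, ND5, ND6 and CYTB. The peaks have a median width of 1398 bp, against 682 bp for nuclear peaks, and cover 8173 bp, or 53.0%, of the sequence up to the end of the last mitochondrial gene. No peak lies in the 6369 bp from 4640 to 11009. A difference in mitochondrial DNA content between the ChIP and the input may give wide peaks over much of the molecule, and the width and cover given here meet that prediction. It made no statement on stretches without a peak. The explanation stays open, since its prediction was written after the peaks were seen. Reads of nuclear copies of mitochondrial DNA cannot be weighed without the sequence, and no biological explanation was tested.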

How the results depend on the processing

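Alternatives on the first 8348 positions, on the peaks at least as wide as the median, on either gene end, on the background, and all those of the position and shift comparisons were chosen after the data were seen. The number of peaks, 16697, became 13101 when peaks within 1 kb were merged and 8354 when only peaks at least as wide as the median were kept. The promoter share of 76.4% was 63.4% with a 500 bp window, 86.0% with a 3 kb window, 79.2% with any base of the peak, 92.2% in the first 8348 positions and 89.5% among wide peaks. Genes with a promoter peak numbered 7048 among wide peaks and between 7211 and 10832 under the other alternatives, against 10601. The fold of peaks near gene ends over shifted peaks was 32.3 with a 500 bp window and 9.88 with a 3 kb window. Lists bound more often numbered 12 to 19 over the alternatives, against 17, and lists bound less often 4 to 8, against 6, the count of 4 standing where the chemosensory and keratin lists were taken out of the test. Of 232 pairs of list and alternative, 208 kept direction and call, 12 lost the call, 4 gained it and 8 turned direction. The odds ratio of epicardial and fibroblast markers turned to 0.972 with a 500 bp window, 0.141 in the first 8348 positions and 0.411 among wide peaks. That of sarcomere genes turned to 0.272 in the first 8348 positions and 0.418 among wide peaks, that of endothelial markers to 0.693 and 0.986, and that of neural crest genes to 0.745 in the first 8348 positions. Settings that keep early or wide peaks remove late or narrow ones. First promoter peaks of sarcomere genes and epicardial markers had median positions of 12371 and 12038 and median widths of 502.5 and 506 bp. Those of endothelial markers (9866) and neural crest genes (9379) also stood late. Why these peaks were late or narrow was not tested, nor was the turn with a 500 bp window. Sarcomere and heart defect genes also lost their call with either gene end, with odds ratios of 1.04 and 1.57. Among wide peaks the cilium list (1.22) and the Zfp list (1.06) lost theirs, and in the first 8348 positions the Zfp list (1.06) and the heart defect list (1.65) did. Neural crest genes were called higher with a 3 kb window (2.39), any base (2.45) and names at any distance (2.70), and endothelial markers with names at any distance (2.48). The 6 lists early in the order kept their call under every window and on the autosomes, while among late lists endothelial markers fell within the random range with a 500 bp window and neuronal genes became late under 4 of 5 alternatives. No paired analysis was possible because there is 1 library of each kind, and none could be left out. Alternatives on q, on fold enrichment, on CpG content and on motifs were not run, since they need values or sequence not used here. Depth is unknown and limits every statement on a gene without a peak.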

Other observations

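The 5 gene lists of this part, the comparison of the X chromosome and the tests of both patterns were chosen after the data were seen. Clock genes had promoter peaks in 23 of 24 cases, 95.8% against 50.5% of other genes (Fisher's exact test, adjusted p = 3.81e-06 over the 5 lists), among them Nr1d2 (position 112), Cry1 (536) and Tef (1408). Immediate early genes had them in 33 of 39 cases, 84.6% (adjusted exact p = 1.48e-05), led by Npas4 (117), Klf10 (549) and Dusp2 (780). Transcription factors of other lineages (neural, endodermal, skeletal muscle and pluripotent cells) had them in 18 of 90 cases, 20% (adjusted exact p = 9.29e-09), at a median position of 12770, and Pax2, Pax4 and Pax5 had no named peak. Genes of tRNA synthetases and tRNA modification had them in 60 of 72 cases, 83.3% (adjusted exact p = 1.48e-08), a list drawn up after the first 40 positions had been read. Members within those positions, among them Trmt61a, Vars and Mettl1, were kept in the count and the test.

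Non-coding genes also had peaks at their starts, among them 284 long non-coding RNA genes, 50 microRNA genes and 21 small nucleolar RNA genes. The earliest of each class were the long non-coding RNA gene 3110056K07Rik (position 49), Snord42b (178) and Mir707 (256), and Tug1 stood at position 859. Many of these lie within or next to protein-coding genes, so a peak can belong to either. On the X chromosome 307 of 905 protein-coding genes had a promoter peak, 33.9%, against 51.3% on the autosomes (odds ratio 0.486, Fisher's exact p = 5.70e-25). Single autosomes ranged from 39.0% on chromosome 7 to 61.0% on chromosome 12, and the cause of these differences was not tested.

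Genes of ribosome biogenesis stood at the front of the list: 81 of 97 had a promoter peak (83.5%), at a median position of 1460 against 5882 for all genes with one. Peak width argues poorly for this as the whole cause, since random lists matched on width had medians between 3914 and 6026 (their central 95%). Start sites shared with a neighbour were present at 24.7% of these genes against 15.5% of all, and random lists matched on this had medians between 4420 and 7177. Without the 10 genes already seen in the first 40 positions, the other 71 had a median position of 1846, earlier than every one of 10000 random lists. A high rate of transcription and CpG-rich promoters stay open, as no expression data or sequence were used, and no biological explanation was tested.

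Cardiac transcription factors with a promoter peak had a mean of 3.31 named peaks within 10 kb against 1.32 over all such genes, and 19 of 36 had 3 or more (52.8% against 5.97%), with 10 at Hand2, 8 at Gata4 and Gata6 and 7 at Nkx2-5 and Rara. Isolation of the genes argues poorly for this, since random lists matched on the gap to the next gene had means between 1.19 and 1.75. Peaks were counted over all start sites named for a gene. No random list was matched on the number of start sites, so its part in the pattern is unknown. With peaks within 1 kb merged, which also joins separate neighbouring elements, the mean was 1.78, above the random range of 1.00 to 1.17, so splitting over such gaps is not the whole cause. Promoter-bound factors of other lineages had a mean of 1.17, within the random range. Clock (2.35), immediate early (2.30), sarcomere (2.83), neural crest (2.14), signalling pathway (1.98) and endothelial genes (1.95) stood above the range of random lists of their own size. So did heart defect (1.90), Sin3 complex and partner (1.85), chromatin (1.78) and epicardial genes (1.75). Some of these lists share members with the cardiac factors, such as Hand2 in the neural crest list and Nkx2-5 and Gata4 in the heart defect list. The sarcomere list shares none. The pattern is thus not particular to cardiac transcription factors, and its cause stays open, as no biological explanation was tested.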
